A study of Xenopus tropicalis with 12 samples.

How the data were processed

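RNA of whole embryos of the frog Xenopus tropicalis (also called Silurana tropicalis), 3 days post fertilization, was measured on 12 single-colour Agilent arrays, 1 sample per array. Per the labels, 4 arrays each came from control embryos, embryos exposed to naphthenic acid mixture S1 and embryos exposed to mixture S2. Naphthenic acids are carboxylic acids obtained from petroleum. The mixtures were separate batches of 1 catalogue product, per the series' design text. Neither the dose nor the length of the exposure is given in the sources used here. Per the labels' protocols, total RNA was extracted with a Qiagen kit and labelled with Cy3 by Agilent's single-colour protocol.

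Per the file headers, the authors' scans were read with Agilent Feature Extraction 11.0.1.1, and the deposited processed signal of each spot is an intensity on a linear scale. The array design names JGI 4.1 as its genome build, per the file headers. Each array holds 45220 features, of which 1417 are control spots and 43803 carry 32899 distinct probes (21995 with 1 spot and 10904 with 2). The authors also deposited a value table in log2 units. Its 12 columns all had the median 6.80, and each column equalled the quantile-normalized log2 of that array's processed signal, with the direction of the array's own signal and no centring of probes. The tool that made this table is not given in the sources used here.

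For the main results, the deposited intensity was taken to log2 and the array's 75th percentile over non-control spots was subtracted. Spots that the scanner software marked as outliers (295 in all) were left out, unless all spots of the probe on that array were marked. In that case they were kept. No spot was saturated, and spots of 1 probe were averaged. Probes well above background on at least 4 of the 12 arrays, in any groups, were tested, 29168 in all. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), in 1 fit over the 12 arrays with no covariate, as S1 minus control, S2 minus control, S2 minus S1, and a moderated F-test over the 3 groups. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Where no array of a group was well above background, the change is given as "at least N-fold", that is the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest signal well above background and the probe's own signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

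Probes carry transcript accessions, which were paired with symbols through a RefSeq gene table of the assembly UCB_Xtro_10.0. Because that assembly differs from the build of the array design, the table served only for names and for which genes neighbour each other, and no coordinates are given. Of the 29168 tested probes, 4594 matched a gene with a symbol (4372 distinct symbols), 861 matched a gene with only a LOC placeholder, which was not counted as a symbol, and 23713 (81.3%) matched no entry. Probe names hold either the word specific (15689 tested) or the word xhyb (13479 tested). The latter is read here as a probe that can cross-hybridise with related transcripts, and such probes are called cross-hybridising below. For a gene with several probes, the probe with the highest mean over all arrays stood for the gene.

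Gene lists for pathways, toxic responses and cell types were fixed, 48 in number, and 38 had at least 5 measured genes and were tested with camera (limma) over the 4372 named genes, with a preset correlation of 0.01 between genes. The tests with an estimated correlation and with fry were also run. The named genes followed a fixed rule. It took, in each comparison with control, the 12 largest rises and 12 largest falls among genes with a symbol that passed and whose 4 arrays per group did not overlap, then up to 4 passing genes per list. Where fewer than 10 genes passed, it took the 5 rises and 5 falls with the smallest unadjusted p. Some genes known to respond to chemicals were added whatever their result. Some of the genes that the rule takes are not reported here. The groups, the tests, the lists, this rule and most of the alternative settings were fixed before the data were examined.

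The list test and the probe tests were tried on simulated data first. With 200 probes changed by known amounts among the 29168 in the comparison of S1 with control, limma called 32% at a log2 change of 0.5, 64% at 1, 96% at 2 and 98% at 3. Among the 28968 unchanged probes it made 4 false calls in S1 against control, 0 in S2 against control and 9 in S2 against S1. The simulated noise was independent between probes and arrays, with no effect of the slides. These counts therefore do not show how many false calls the real arrays give. Alternatives covered the background correction, the scaling, the authors' table, the filter on dim probes, the slide and the replicate number as blocks, array weights, the prior variance, the threshold, probes of a gene, and leaving out each array in turn. Added after the data were seen were array brightness as a covariate, specific probes only, leaving out the 3 arrays that stood apart, leaving out 3 doubtful list matches, and forms of the background correction by normexp on the median signal of a spot, since the mean signal was not used here.

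Brightness differed between arrays, and the number of arrays limits the precision of every value. The labels do not say whether the 4 samples of a group came from separate clutches, tanks or pools of embryos, so p-values measure only the spread between these samples, which may be technical.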

Results

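The series asked how gene expression in Xenopus tropicalis embryos responded to mixtures of naphthenic acids. It held 4 arrays per group, on 3 slides of 4 arrays each. Slide 1 held C-1, S1-1, S2-1 and S2-2. Slide 2 held C-2, S1-2, S1-3 and S2-3, and slide 3 held C-3, C-4, S1-4 and S2-4, where C stands for control. The 75th percentile of the signal lay between 500 and 985 on the control arrays, between 261 and 537 on the S1 arrays and between 481 and 675 on the S2 arrays. Mean log2 brightness was 9.44 ± 0.47 (SD, n = 4) in controls, 8.68 ± 0.46 in S1 and 9.11 ± 0.21 in S2. By a two-sided exact permutation test control against S1 gave p = 0.0571 (0.171 adjusted over 6 tests), control against S2 p = 0.257 and S1 against S2 p = 0.114. On average 88.8%, 85.2% and 85.5% of probes were well above background in controls, S1 and S2.

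Arrays of a group correlated at r = 0.978 to 0.992 across probes (median 0.987) and arrays of different groups at 0.977 to 0.992 (median 0.983); probes are not independent replicates. The first principal component held 26.7% of the variance and the next 18.0%. C-3 lay apart from the other arrays on the first component (score 60.5), S1-4 on the next (55.0) and S2-4 on the one after (-56.6). The first component also went with the slide. Its scores ran from -41.1 to 3.47 on slide 1, from -22.9 to 14.3 on slide 2 and from 3.51 to 60.5 on slide 3. Without these 3 arrays the counts of probes changed in S1 against control and of probes changed in S2 against control were 411 and 995. The median 95% interval of a log2 fold change reached 0.32 to either side of the estimate.

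In embryos exposed to mixture S1, the cytochrome P450 gene cyp2c19, the efflux pump gene abcg2 and the chemokine genes cxcl9 and cxcl11 gave higher signals than in control embryos, and the keratin gene krt78.1 and the cartilage gene cytl1 gave lower ones. The probe of cyp2c19, which encodes an enzyme of a family that oxidises drugs and other foreign compounds, rose by 2.27 ± 0.12 on the log2 scale (SE, n = 4 arrays per group, limma adjusted p = 3.83e-07). abcg2 rose by 1.52 ± 0.14 (adjusted p = 0.000109) and cxcl11 by 3.01 ± 0.31 (adjusted p = 0.000227). krt78.1 fell by 1.85 ± 0.27 (adjusted p = 0.00347) and cytl1, a secreted factor of cartilage, fell by 1.28 ± 0.15 (adjusted p = 0.000687). These 5 genes moved in the same direction within each of the 3 slides. The rule that took them fixes this, since it asks that the arrays of the 2 groups do not overlap. None of the 5 passed after a normexp background correction on the local backgrounds as measured, where cyp2c19 stood at 1.01, abcg2 at 0.99, cxcl11 at 1.32, krt78.1 at -0.80 and cytl1 at -0.66 (adjusted p = 0.784, 0.645, 0.784, 0.784 and 0.784), and all 5 passed when outlying local backgrounds were replaced. With the backgrounds as measured, the lowest percentile of the corrected signals ran from 56.8 to 1316.7 between arrays, against 35 to 50 before. A call lost under that form, here and below, therefore cannot be read as the absence of a change. With array brightness as a covariate krt78.1 did not pass (-1.49, adjusted p = 0.0821).

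Among the largest rises, cxcl9 was well above background on 0 of 4 control arrays and on all 4 S1 arrays, and was at least 11-fold higher in S1 (adjusted p = 0.000487). That bound depends on the background correction. The log2 change of cxcl9 was 1.24 (adjusted p = 0.00172) after normexp with outlying local backgrounds replaced, and 0.86 (adjusted p = 0.784) with them kept. The cross-hybridising probes of cyp2f1 and cyp2a13l rose by 2.56 ± 0.12 and 2.53 ± 0.12 (adjusted p = 1.12e-07 and 9.37e-08), and that of rbm48, an RNA-binding protein gene, by 2.59 ± 0.11 (adjusted p = 4.73e-08). npc1l1, which encodes a sterol uptake protein, rose by 1.32 ± 0.23 (adjusted p = 0.0134). mov10, an RNA helicase gene, rose by 1.84 ± 0.33 and was well above background on 2 of 4 control arrays. The remaining large rises were in acod1la (2.16 ± 0.49, well above background on 1 of 4 control arrays), xa-1 (1.81 ± 0.36) and, on a cross-hybridising probe, phyhdlb (1.29 ± 0.26).

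Among the largest falls, aqp10, an aquaporin gene, fell by 0.95 ± 0.11 (adjusted p = 0.000792), the phosphate cotransporter genes slc34a3 and slc34a2 fell by 0.93 and 0.91, the latter on a cross-hybridising probe, and the chloride channel gene clcn2 fell by 0.79. The photopigment gene pinopsin100496420 fell by 0.88, synm, which encodes an intermediate filament protein, fell by 0.80, and spata45 fell by 0.80. sec61b, on a cross-hybridising probe, fell by 0.93, c4h3orf84 fell by 0.77 and lrrc52 fell by 0.74. After normexp with outlying local backgrounds replaced aqp10, slc34a2, c4h3orf84 and lrrc52 did not pass. With those backgrounds kept none of the genes in this paragraph passed. The sign then turned for aqp10 (0.0902), c4h3orf84 (0.24) and lrrc52 (0.28).

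Of the cytochrome P450 list of families 2, 3 and 4, the probes of 3 of 11 measured genes rose (cyp2c19 and, cross-hybridising, cyp2a13l and cyp2f1) and 8 did not pass; adjusted over the list alone, 4 rose and 2 fell. The list's mean was 0.68 and its median 0.07 (camera adjusted p = 0.00237; adjusted p = 0.113 with an estimated correlation; slide means 0.76, 0.67 and 0.61; with slide as a block 0.66, adjusted p = 0.0185). On specific probes alone its mean was 0.45 (adjusted p = 0.0537). Of 11 drug and bile acid transporters, abcg2 rose and 10 did not pass, and 3 rose when adjusted over the list alone. The anion transporter gene slc22a6 stood at 0.70 (adjusted p = 0.0732) and the bile acid transporter subunit gene slc51b, cross-hybridising, at 0.54 (adjusted p = 0.0699). The transporters rose as a list by a mean of 0.31 (adjusted p = 0.0114; adjusted p = 0.239 with an estimated correlation; slide means 0.51, 0.20 and 0.39; with slide as a block 0.34, adjusted p = 0.0181). With array brightness as a covariate the mean was 0.15 and the call was lost (adjusted p = 0.122).

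Of 13 lipoprotein and lipid transport genes, ldlr, the receptor of low-density lipoprotein, rose by 0.51 ± 0.10 (adjusted p = 0.0237) and 12 did not pass; adjusted over the list alone, 1 rose. The list rose by a mean of 0.20 (adjusted p = 0.00981; adjusted p = 0.239 with an estimated correlation; slide means 0.25, 0.12 and 0.27; with slide as a block 0.21, adjusted p = 0.0181). Of 15 liver markers, 2 rose and 13 did not pass, over all genes and adjusted over the list alone. They were plg, which encodes plasminogen (0.65 ± 0.15, adjusted p = 0.0456), and kng1, which encodes kininogen (0.78 ± 0.18, adjusted p = 0.0481). The liver list rose by a mean of 0.20 (adjusted p = 0.0273; adjusted p = 0.239 with an estimated correlation; slide means 0.15, 0.31 and 0.08), and this call was lost under quantile normalization and in the authors' table (both 0.19, adjusted p = 0.0537), with slide as a block (0.20, adjusted p = 0.118), without S1-2 (adjusted p = 0.102) and without C-3 (adjusted p = 0.113).

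Lens markers fell as a list by a mean of 0.93 (adjusted p = 0.00237; adjusted p = 0.296 with an estimated correlation), although none of the 11 measured genes passed over all genes and 8 fell when adjusted over the list alone. The slide means were -1.24, -0.82 and -0.69, and the mean with slide as a block was -0.87 (adjusted p = 0.00192). The filament genes bfsp1 and bfsp2 stood at -1.74 (adjusted p = 0.0843) and -1.51 (adjusted p = 0.0994), and the crystallin genes cryga.6 and cryga.7 at -1.69 and -1.68. Of 9 cartilage and bone markers, cytl1 fell and 8 did not pass, and 3 fell when adjusted over the list alone. That list fell by a mean of 0.33 (adjusted p = 0.0273; adjusted p = 0.239 with an estimated correlation; slide means -0.31, -0.25 and -0.31; with slide as a block -0.29, adjusted p = 0.0459), and the call was lost without C-3 (adjusted p = 0.0908).

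No member passed in 3 further lists that camera called. Neuron markers (12 genes) fell by a mean of 0.21 (adjusted p = 0.0273; adjusted p = 0.239 with an estimated correlation), with slide means of -0.14, -0.36 and -0.08, and 2 fell when adjusted over the list alone. Myeloid markers (6 genes) rose by a mean of 0.35 and inflammation genes (9 genes) by 0.42 (both adjusted p = 0.0273; both adjusted p = 0.239 with an estimated correlation), with 2 members rising in each when adjusted over the list alone. The slide means were 0.30, 0.45 and 0.28 for the myeloid list and 0.21, 0.84 and 0.28 for the inflammation list. With slide as a block the means of the neuron, myeloid and inflammation lists were -0.19, 0.35 and 0.46 (adjusted p = 0.0459, 0.0473 and 0.0459). The chemokine gene cxcl10 stood at 1.92 (adjusted p = 0.0853), and mpo, which encodes myeloperoxidase and is in both of these lists, at 0.56 (adjusted p = 0.0811). Without S1-2 the neuron, myeloid and inflammation calls were all lost (adjusted p = 0.071 each), as were the neuron call without C-2 (adjusted p = 0.0579) and the inflammation call without S1-3 (adjusted p = 0.0553).

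Single genes passed in lists that camera did not call or, for rps19, in a list with too few measured genes to be tested. hsp90b1, a chaperone gene of the endoplasmic reticulum, rose by 0.65 ± 0.11 (adjusted p = 0.00969). amn, which encodes a partner of cubilin in the kidney and gut, rose by 0.69 (adjusted p = 0.0408) and the ribosomal protein gene rps19, on a cross-hybridising probe, by 0.63. rbp3, a retinoid-binding protein gene of the retina, fell by 0.48 ± 0.09 (adjusted p = 0.0175), the small heat shock protein gene hsp30c fell by 0.67 on a cross-hybridising probe, hnf4g fell by 0.64, the retinoic acid receptor gene rarb fell by 0.45 and ift88, a gene of ciliary transport, fell by 0.45.

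In total, 612 of the 29168 tested probes passed in S1 against control, 407 higher and 205 lower, of which 155 and 35 changed at least 2-fold. They covered 99 genes with a symbol (60 higher, 39 lower), and 476 had no match to a gene. All 612 moved in the same direction within the 3 slides, which being called on these same arrays favours, and with slide as a block 555 passed. The count was 393 without S2-1, 376 without S1-1, 349 without C-1, 294 without C-2, 386 without S2-3, 277 without S1-3, 379 without C-3 and 333 without C-4. Of the 35 genes named above with a call, 15 passed whichever array was left out, namely cxcl9, cxcl11, rbm48, cyp2f1, cyp2a13l, cyp2c19, abcg2, npc1l1, krt78.1, cytl1, aqp10, synm, spata45, c4h3orf84 and hsp90b1. Of the 12 such sets, acod1la, rps19 and kng1 passed in 1, lrrc52, hsp30c, rarb, plg and amn in 2, slc34a3, sec61b, slc34a2, pinopsin100496420 and ift88 in 3, hnf4g in 4, xa-1 in 5, phyhdlb in 7, ldlr in 8, clcn2 and rbp3 in 10 and mov10 in 11. With slide as a block 29 of the 35 passed, all but phyhdlb, pinopsin100496420, lrrc52, rarb, plg and kng1. After normexp with outlying local backgrounds replaced 24 passed, all but acod1la, aqp10, slc34a2, c4h3orf84, lrrc52, ldlr, rps19, hsp30c, rarb, hnf4g and ift88, and with those backgrounds kept only 3 passed, rbm48, cyp2f1 and cyp2a13l. With array brightness as a covariate 11 passed, namely cxcl9, cxcl11, rbm48, cyp2f1, cyp2a13l, cyp2c19, abcg2, npc1l1, cytl1, aqp10 and c4h3orf84, and the other 24 did not.

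**Figure D1:**
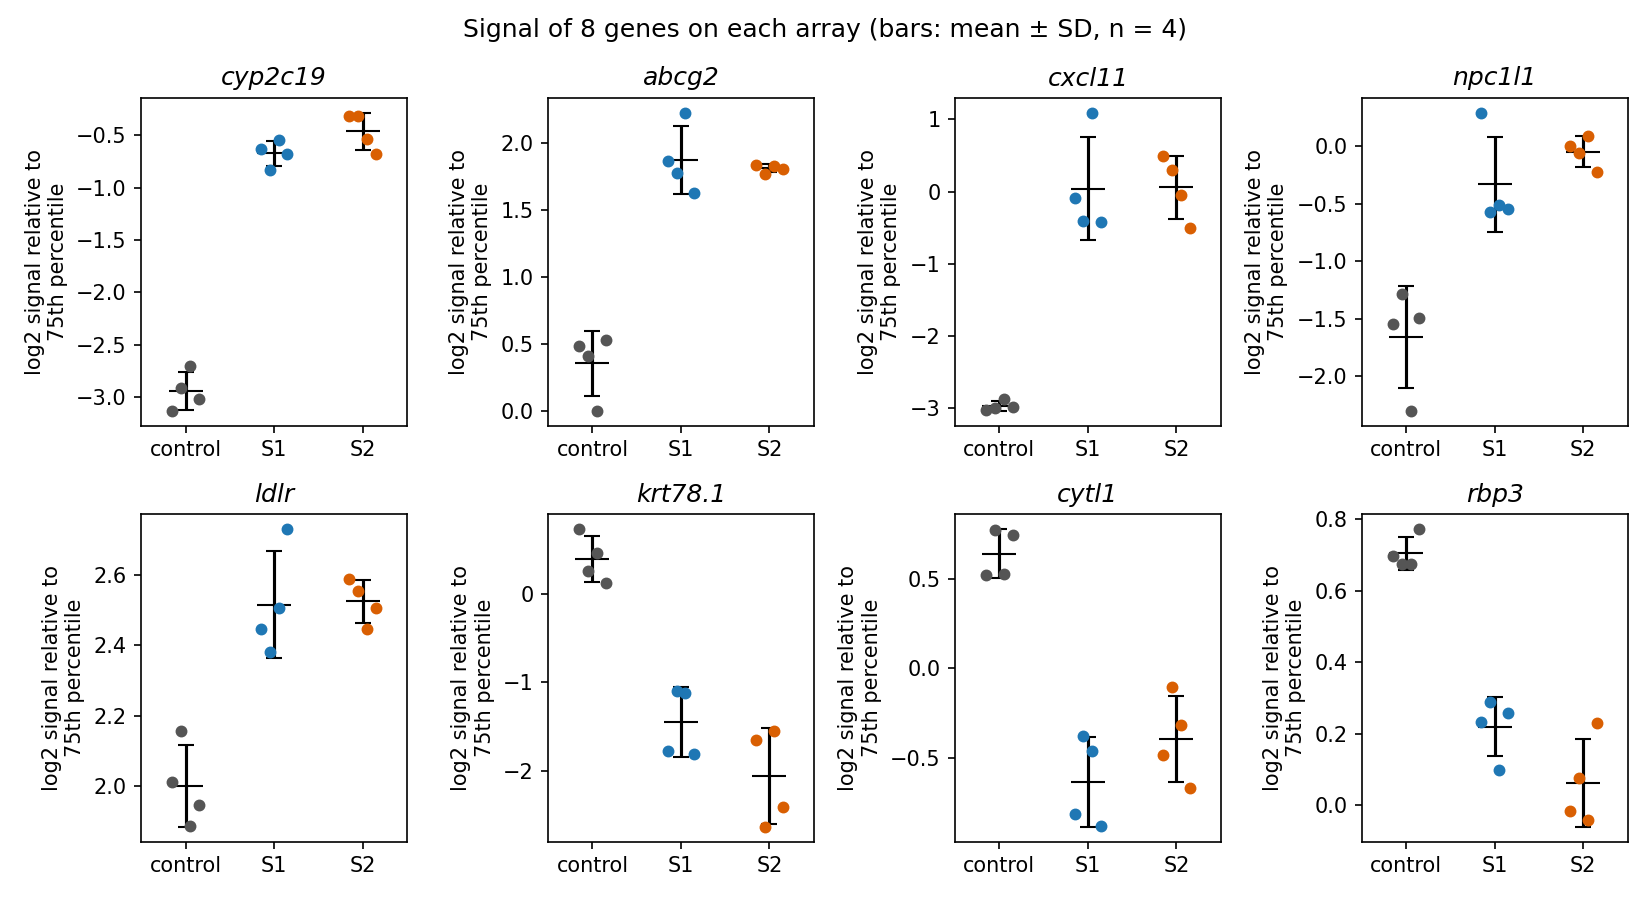
Signal of 8 genes on each array (vertical axis, log2 signal relative to the array's 75th percentile) by group (horizontal axis), with bars for the mean ± SD of 4 arrays. For cyp2c19, abcg2, cxcl11, npc1l1 and ldlr the S1 and S2 arrays lie above the control arrays, and for krt78.1, cytl1 and rbp3 below them.

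In embryos exposed to mixture S2, cyp2c19, abcg2, cxcl11 and npc1l1 gave higher signals than in control embryos, as did 4 of 13 lipoprotein and lipid transport genes, and krt78.1 and the retinal gene rbp3 gave lower ones. cyp2c19 rose by 2.48 ± 0.12 (SE, n = 4 arrays per group, limma adjusted p = 1.44e-07), abcg2 by 1.46 ± 0.14 (adjusted p = 0.00014) and cxcl11 by 3.02 ± 0.31 (adjusted p = 0.00019). npc1l1 rose by 1.60 ± 0.23 (adjusted p = 0.00299). krt78.1 fell by 2.46 ± 0.27 (adjusted p = 0.000283), and inhbc.1, which encodes an inhibin subunit of the transforming growth factor family, fell by 1.99 ± 0.25 (adjusted p = 0.000872). These 6 genes moved in the same direction within each of the 3 slides, which the rule of arrays that do not overlap again fixes. After normexp with the local backgrounds kept none of the 6 passed, with cyp2c19 at 1.06, abcg2 at 1.04, cxcl11 at 1.33, npc1l1 at 0.86, krt78.1 at -1.20 and inhbc.1 at -0.17 (adjusted p = 0.37 for abcg2 and 1 for the others). With outlying local backgrounds replaced all but inhbc.1 passed (-0.62, adjusted p = 0.0869).

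Of the other large rises, cxcl9 was at least 9.75-fold higher in S2 (adjusted p = 0.000605), again with 0 of 4 control arrays well above background. Its log2 change was 0.98 (adjusted p = 0.00972) after normexp with outlying local backgrounds replaced, and 0.47 (adjusted p = 1) with them kept. The cross-hybridising probes of cyp2f1, cyp2a13l and rbm48 rose by 2.68, 2.67 and 2.64, and mov10 rose by 1.77 (adjusted p = 0.0136). arsa.2, an arylsulfatase gene, rose by 1.53 ± 0.30 (adjusted p = 0.0154), entpd5, a nucleotide diphosphatase gene, by 1.21 ± 0.16 (adjusted p = 0.00189) and bco1, which encodes a carotene-cleaving oxygenase, by 1.17 ± 0.19 (adjusted p = 0.00617).

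The largest falls also held atp13a-like, which fell by 1.51 ± 0.26 (adjusted p = 0.00797), the lens crystallin gene cryga.1, which fell by 1.31 ± 0.34 (adjusted p = 0.0478), stpg4, which fell by 1.20 ± 0.14, and spata45, which fell by 1.16 (adjusted p = 0.00023). Falls of 1.06 to 1.16 were measured for lrrd1 (-1.16), cnp (-1.13), slc49a4 (-1.12), lrrc14b (-1.10), ppp1r32 (-1.06) and mss51 (-1.06). After normexp with outlying local backgrounds replaced, the changes of cryga.1, atp13a-like and stpg4 were -0.15, -0.18 and -0.15, those of lrrd1, cnp and lrrc14b were -0.13, -0.18 and -0.38, that of ppp1r32 was -0.54 (adjusted p = 0.0552), and none of these 7 passed. With those backgrounds kept the sign turned for all of them but ppp1r32 (0.14, 0.08, 0.10, 0.11, 0.09 and 0.36 in the order given), and slc49a4, mss51 and spata45 did not pass either.

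Of the 13 lipoprotein and lipid transport genes, 4 rose and 9 did not pass; adjusted over the list alone, 5 rose. The risers were apob, which encodes the structural protein of low-density lipoprotein (0.73 ± 0.17, adjusted p = 0.0348), the receptor genes lrp2 (0.58, adjusted p = 0.0171) and ldlr (0.52, adjusted p = 0.0146), and scarb1, a receptor of high-density lipoprotein (0.36, adjusted p = 0.049). As a list they rose by a mean of 0.32 (camera adjusted p = 0.000383; adjusted p = 0.0667 with an estimated correlation; slide means 0.34, 0.21 and 0.35; with slide as a block 0.31, adjusted p = 0.000665). Of the 15 liver markers, apob, kng1 (0.86, adjusted p = 0.0206) and plg (0.82, adjusted p = 0.011) rose and 12 did not pass, with 4 rising when adjusted over the list alone. The liver list rose by a mean of 0.28 (adjusted p = 0.00428; adjusted p = 0.21 with an estimated correlation; slide means 0.18, 0.33 and 0.37; with slide as a block 0.28, adjusted p = 0.0122). apob is a member of both lists, and alb, the serum albumin gene, stood at -0.25 on a cross-hybridising probe (adjusted p = 0.473).

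The probes of the cytochrome P450 genes cyp2c19, cyp2a13l and cyp2f1, the latter pair cross-hybridising, rose and those of the other 8 of the 11 did not pass; adjusted over the list alone, 6 rose and 2 fell. The list's mean was 0.75 (adjusted p = 0.00137; adjusted p = 0.0667 with an estimated correlation; slide means 0.80, 0.81 and 0.62; with slide as a block 0.73, adjusted p = 0.00329). The median of the cytochrome P450 list was 0.30, with 6 genes above 0 and 5 below. Of the 11 transporters abcg2 alone passed over all genes, and 4 rose and 1 fell when adjusted over the list alone. The transporter list rose by a mean of 0.29 (adjusted p = 0.005; adjusted p = 0.21 with an estimated correlation; slide means 0.49, 0.24 and 0.23; with slide as a block 0.33, adjusted p = 0.00329). Of 12 pronephros markers, genes of the larval kidney, lrp2 and amn (0.78, adjusted p = 0.0162) rose and 10 did not pass, with 3 rising when adjusted over the list alone. That list shares lrp2 with the lipoprotein list and rose by a mean of 0.23 (adjusted p = 0.0357; adjusted p = 0.21 with an estimated correlation; slide means 0.35, 0.15 and 0.22; with slide as a block 0.25, adjusted p = 0.0286). The pronephros call was lost without C-1, C-4 or S2-4 (adjusted p = 0.0581, 0.0571 and 0.0517).

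Lens markers fell by a mean of 0.92 (adjusted p = 0.00944; adjusted p = 0.423 with an estimated correlation), with cryga.1 passing over all genes and 6 of 11 falling when adjusted over the list alone. The slide means were -1.45, -0.50 and -0.22, and with slide as a block the mean was -0.75 (adjusted p = 0.0116). Of 16 photoreceptor and retina markers, rbp3 (-0.64, adjusted p = 0.00218), rom1, a gene of the outer segment discs (-0.53, adjusted p = 0.0195), and the guanylate cyclase gene gucy2f (-0.48, adjusted p = 0.0403) fell and 13 did not pass, over all genes and adjusted over the list alone. The photoreceptor list fell by a mean of 0.21 (adjusted p = 0.0376; adjusted p = 0.423 with an estimated correlation; slide means -0.02, -0.25 and -0.26; with slide as a block -0.17, adjusted p = 0.0399). Its call was lost without C-2, C-3, C-4, S2-3 or S2-4 (adjusted p = 0.0507, 0.0787, 0.0571, 0.0833 and 0.0963).

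Of 13 epidermis markers, krt78.1 and, on a cross-hybridising probe, krt78.3 (-0.52, adjusted p = 0.0364) fell and 11 did not pass, with 4 falling when adjusted over the list alone. The epidermis list fell by a mean of 0.47 (adjusted p = 0.017; adjusted p = 0.23 with an estimated correlation; slide means -0.51, -0.24 and -0.47; with slide as a block -0.43, adjusted p = 0.014). Of the 9 cartilage and bone markers, cytl1 fell by 1.04 (adjusted p = 0.003), fgfbp2 fell by 0.63 (adjusted p = 0.0438) and 7 did not pass, with 2 falling when adjusted over the list alone. The cartilage list fell by a mean of 0.39 (adjusted p = 0.0166; adjusted p = 0.227 with an estimated correlation; slide means -0.28, -0.34 and -0.42; with slide as a block -0.34, adjusted p = 0.0116).

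**Figure D2:**
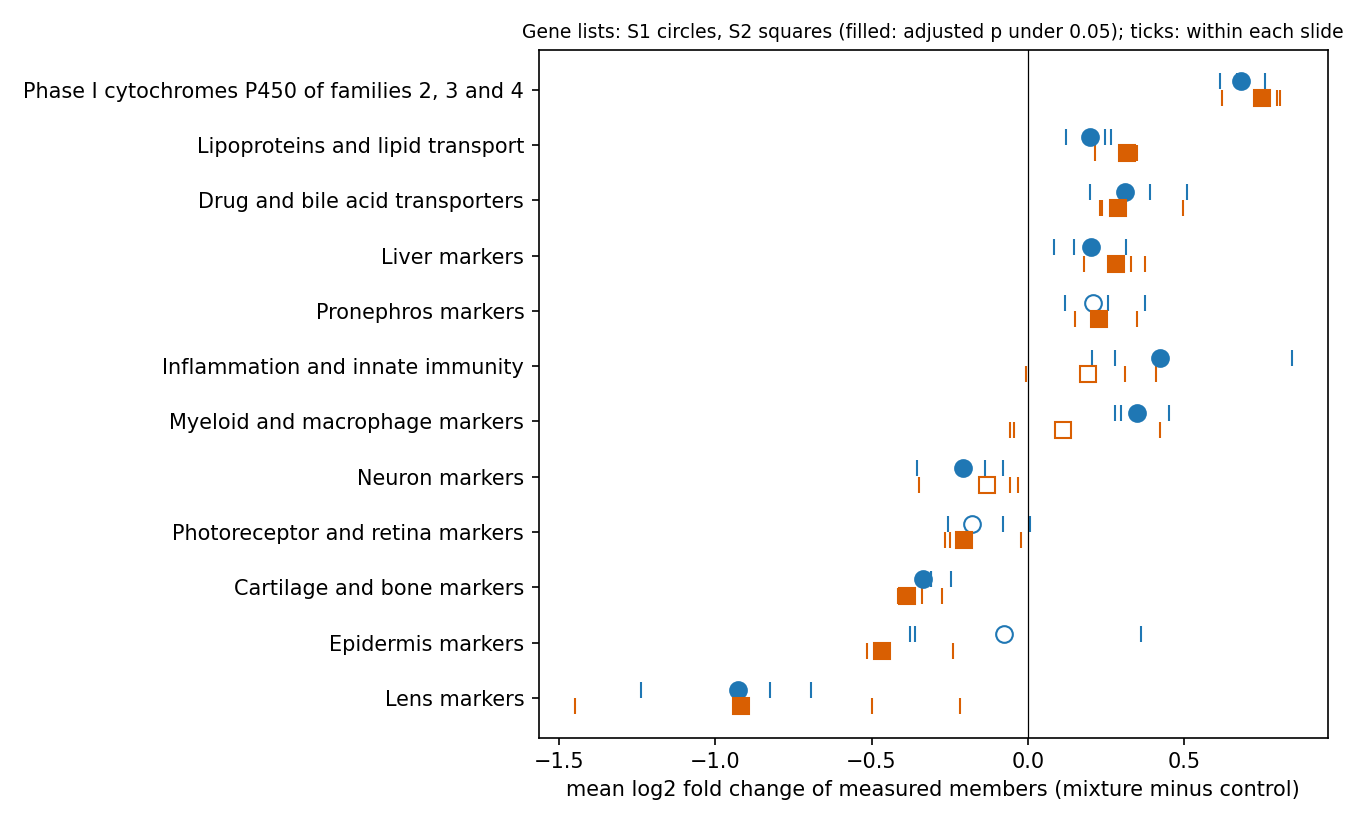
Mean log2 fold change against control (horizontal axis) of the 12 gene lists that camera called in either mixture (vertical axis), with circles for S1, squares for S2, filled symbols for lists called at an adjusted p under 0.05 and ticks for the means within each slide. The cytochrome P450 list lies at 0.68 and 0.75, and the lens list at -0.93 and -0.92.

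Outside the called lists, pvalb, which encodes parvalbumin, fell by 0.95 (adjusted p = 0.0309) and ampd1, which encodes the muscle AMP deaminase, fell by 0.80 (adjusted p = 0.00927). atf6, a sensor of the unfolded protein response, rose by 0.70 (adjusted p = 0.018) and chac1, a target of that response, fell by 0.58 (adjusted p = 0.0218). me1, the malic enzyme gene, rose by 0.57, angptl4, which encodes an inhibitor of lipoprotein lipase, by 0.56, the bile acid receptor gene nr1h4 by 0.49, mpo by 0.58, rps19 by 0.69 and oxt, the gene of an oxytocin-type hormone, by 0.47. kif5c, a kinesin gene of neurons, fell by 0.86 (adjusted p = 0.0148), ift88 fell by 0.45 and the survival gene mcl1 fell by 0.50. On cross-hybridising probes, the chymotrypsinogen gene ctrb1 fell by 1.01 (adjusted p = 0.0219), vcan fell by 0.43 and the pigment cell gene mlana fell by 0.49 (adjusted p = 0.0442), with a further mlana probe at -0.38 (adjusted p = 0.0649).

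In total, 1476 of the 29168 probes passed in S2 against control, 710 higher and 766 lower, of which 151 and 106 changed at least 2-fold. They covered 239 genes with a symbol (106 higher, 133 lower), and 1179 had no match to a gene. Within the 3 slides 1475 of the 1476 kept their direction, which calling likewise favours, and with slide as a block 1049 passed. The count was 482 without S2-1, 519 without S2-2, 845 without C-1, 765 without S2-3, 591 without C-3 and 755 without C-4. Of the 53 genes named above with a call, 23 passed whichever array was left out, among them cxcl11, cyp2c19, abcg2, npc1l1, entpd5, bco1, krt78.1, inhbc.1, spata45, plg, ampd1, kif5c, rbp3 and cytl1. Of the 12 such sets, scarb1 passed in 0, lrrc14b in 1, mpo, mlana and oxt in 2, lrrd1 and fgfbp2 in 3, cryga.1, me1 and gucy2f in 4, slc49a4, angptl4, nr1h4, mcl1, pvalb and vcan in 5, krt78.3 in 6, cnp, chac1, ctrb1 and ift88 in 7, apob, kng1 and rom1 in 8, lrp2 in 9, arsa.2, ldlr and atf6 in 10, and rps19 and amn in 11. With slide as a block 40 of the 53 passed, all but cryga.1, lrrd1, lrrc14b, me1, angptl4, apob, scarb1, nr1h4, mpo, gucy2f, krt78.3, fgfbp2 and vcan. After normexp with outlying local backgrounds replaced 26 passed. The 27 that did not held mov10, inhbc.1, atp13a-like, cryga.1, stpg4, lrrd1, cnp, lrrc14b, ppp1r32, me1, angptl4, ldlr, scarb1 and nr1h4. They also held rps19, chac1, mcl1, mpo, amn, ctrb1, kif5c, gucy2f, ift88, fgfbp2, vcan, mlana and oxt. With those backgrounds kept only 3 passed, cyp2f1, cyp2a13l and rbm48. With array brightness as a covariate 44 passed, all but lrrd1, slc49a4, angptl4, scarb1, mcl1, krt78.3, vcan, mlana and oxt.

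Several genes known to respond to chemicals did not pass in either mixture. The heme oxygenase gene hmox1 stood at -0.20 in S1 and -0.14 in S2 (adjusted p = 0.485 and 0.572), the chaperone gene hspa5 at 0.55 and 0.44 (adjusted p = 0.135 and 0.172), cpt1a, which carries fatty acids into mitochondria, at 0.46 and 0.52 (adjusted p = 0.116 and 0.0565) and cyp3a4.2 at 0.59 and 0.62 (adjusted p = 0.205 and 0.145). cpt1a in S2 passed under 6 alternatives, among them scaling to the median (0.55, adjusted p = 0.0459), and cyp3a4.2 in S2 passed with array weights (0.61, adjusted p = 0.0289) and with brightness as a covariate (0.81, adjusted p = 0.0375). In S1 hspa5 passed without S2-4 (adjusted p = 0.0235) and cyp3a4.2 without S1-4 (adjusted p = 0.0478). alb stood at 0.06 in S1 (adjusted p = 0.915), a value that turned negative under 5 alternatives.

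The direct comparison of the mixtures, which are batches of 1 product, asked whether embryos responded differently to them. No gene passed it. The symbols with the smallest unadjusted p on the higher side in S2 were gpr65, an acid-sensing receptor gene with a cross-hybridising probe (0.55, 95% interval 0.31 to 0.78, adjusted p = 0.352), nim1k (0.56, 0.29 to 0.82), jakmip2 (0.38, 0.17 to 0.59), aqp10 (0.43, 0.18 to 0.68) and septin3 (0.36, 0.15 to 0.56). On the lower side were inhbc.1 (-1.13, -1.67 to -0.59, adjusted p = 0.392), rhbdf1 (-0.46, -0.69 to -0.23), rimklb (-0.63), hexim1 (-0.38) and tmed2 (-0.34). limma called 0 of 29168 probes (2142 at an unadjusted p under 0.05, smallest adjusted p = 0.0746), and 1 without S2-1. Camera called 0 of 38 lists (5 at an unadjusted p under 0.05) and fry 0. The list with the smallest adjusted p was epidermis, with a mean of -0.39 (adjusted p = 0.155), followed by lipoproteins (0.12, adjusted p = 0.225) and neurons (0.08, adjusted p = 0.225).

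Probes called in both mixtures numbered 316 higher and 146 lower, where 9.91 and 5.38 would overlap between independent lists of these sizes. At most 0 were shared in 100 simulations of unchanged groups against common controls with independent noise. Unchanged groups give almost no calls to share, and independent lists have no controls in common. Neither figure therefore measures the overlap that common controls bring between lists of these sizes. Of the probes called in both, 0 went in opposite directions, a result that the common controls favour. Among these 462 probes the median absolute log2 change was 0.76 in S1 and 0.79 in S2, and the median absolute difference between the mixtures was 0.11 against a median 95% interval reaching 0.28 to either side. Unadjusted intervals of the difference excluded 0 for 61 of the 462, and 253 had the larger change in S2.

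Across the 29168 probes the fold changes of S1 and S2 correlated at r = 0.771, with a covariance of 0.0956. Both comparisons share the control arrays. Simulated unchanged groups against those controls gave a mean r of 0.501 with independent noise and 0.451 with resampled arrays (-0.586 to 0.937 over 100 simulations), and mean covariances of 0.0277 and 0.0272 (the latter ranging from -0.0140 to 0.120). The observed covariance exceeded the resampled mean by 0.0684. With 2 controls for each mixture, r was 0.323 to 0.581 over the 6 splits (mean 0.493) and the covariance 0.0532 to 0.0808 (mean 0.0719). The F-test over the 3 groups called 878 probes (621 with slide as a block). That count was 397 without S2-1, 434 without S2-2, 392 without C-1, 473 without C-2, 473 without S2-3, 575 without S1-3, 371 without C-3 and 359 without C-4.

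**Figure D3:**
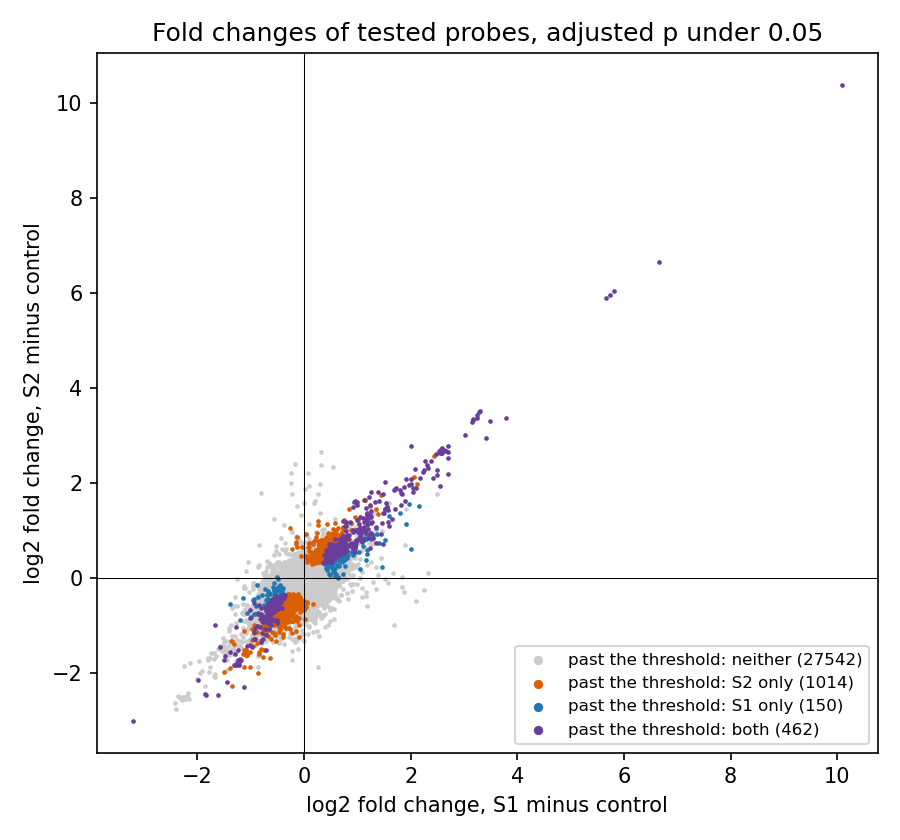
Log2 fold change in S1 (horizontal axis) against that in S2 (vertical axis) for each tested probe, with the 462 probes called in both mixtures set apart from the rest. Probes called in both lie in the upper right and lower left corners, and 0 changed in opposite directions, which the common controls favour.

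The list calls rest on a preset correlation between genes. Camera called 9 of 38 lists in S1 (6 up, 3 down) and 9 in S2 (5 up, 4 down), and 0 in either with an estimated correlation, where the smallest adjusted p was 0.113 in S1 and 0.0667 in S2. fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, called 17 lists in S1 and 12 in S2, and its test for changes in either direction called 21 and 22. With slide as a block camera called 8 lists in S1 and 11 in S2. After the normexp correction with outlying local backgrounds replaced, the calls of lipoproteins (adjusted p = 0.203), liver (adjusted p = 0.786) and myeloid genes (adjusted p = 0.0574) in S1 and of the pronephros in S2 (adjusted p = 0.356) were lost. Their means were 0.26, 0.23 and 0.46 in S1 and 0.17 in S2. The median of all probes moved upward by 0.18 in S1 and 0.12 in S2 under this form. With brightness as a covariate the inflammation (adjusted p = 0.122), myeloid (adjusted p = 0.122) and neuron (adjusted p = 0.102) calls in S1 were lost. The inflammation and myeloid means shrank from 0.42 and 0.35 to 0.20 and 0.17, while the neuron mean went from -0.21 to -0.29. On probes well above background on all 12 arrays the inflammation call in S1 (adjusted p = 0.0574) and the photoreceptor (adjusted p = 0.0519) and pronephros (adjusted p = 0.0973) calls in S2 were lost. So were the pronephros call without a filter on dim probes (adjusted p = 0.0607), the photoreceptor call with array weights (adjusted p = 0.119) and the cartilage call in S1 on specific probes (adjusted p = 0.0537). After normexp with the local backgrounds kept the lipoprotein, liver, inflammation, myeloid and neuron calls in S1 (adjusted p = 0.588, 0.663, 0.187, 0.417 and 0.187) and the photoreceptor and pronephros calls in S2 (adjusted p = 0.0753 and 0.884) were lost. In the same order the means were 0.27, 0.21, 0.58, 0.53 and 0.16 in S1 and 0.03 and 0.15 in S2. The median of all probes moved upward by 0.27 in S1 and 0.19 in S2 there. Without C-3, S1-4 and S2-4 the cartilage call in S1 (adjusted p = 0.0553) and the epidermis (adjusted p = 0.0585) and photoreceptor (adjusted p = 0.21) calls in S2 were lost.

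**Figure D4:**
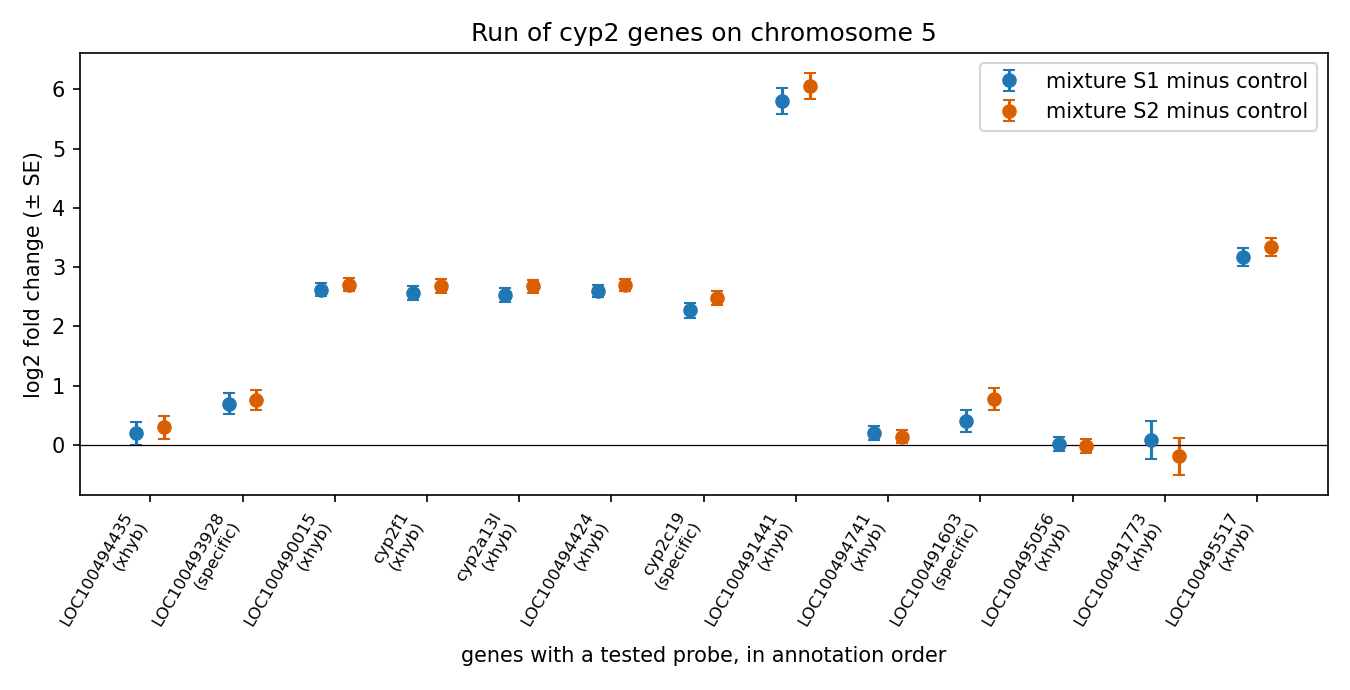
Log2 fold change against control (± SE, n = 4 arrays per group) in S1 and S2 of the 13 genes with a tested probe in a run on chromosome 5. The run holds cyp2 genes, and its genes were chosen after their values were seen. In 7 of the 13 the probe rose in both mixtures, 6 of them on cross-hybridising probes.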

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

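The test on the specific probes of the cyp2 genes and the fit with brightness as a covariate were chosen only after the results were seen.

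For 11 of the 255 sets of 4 arrays examined, for the named genes and for measures of array quality, 1 array lay far from the other 3. Chance gives about 12.8 (about 1 in 20) for sets not chosen by their values, but many named genes were taken because their groups did not overlap. The value for each is the gap to the nearest array divided by the range of the 4 arrays. Among controls C-4 stood apart for rbm48 (0.914) and cyp2f1 (0.908), and C-2 for lrp2 (0.905) and ampd1 (0.892). In S1 the array was S1-2 for cyp2f1 (0.841) and S1-1 for npc1l1 (0.929) and spata45 (0.887). In S2 it was S2-3 for aqp10 (0.964), S2-1 for hsp30c (0.896), and S2-2 for rarb (0.883) and mlana (0.847).

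Other splits of the arrays were counted for each comparison. Of the 35 splits of the 8 control and S1 arrays only the real one (1) gave as many as 612 probes. The highest other gave 18. The same held for S2 against control, where the real split gave 1476 probes and the highest other 0. So few splits cannot give a share under 1 in 35, and they move arrays freely between slides. They make a chance division unlikely as the source of the probe counts but do not exclude it. For the lists with a preset correlation, 1 of 35 splits, the real one, gave 9 calls in each mixture. The highest other gave 5 in S1 and 6 in S2, so chance is not excluded there either. With an estimated correlation the real split gave 0 list calls in either mixture (smallest adjusted p = 0.113 in S1 and 0.0667 in S2), and the splits were not run that way. Between the mixtures the real split gave 0 probes and 0 lists, with 4 probes and 3 lists as the highest other. All 35 splits reach 0 by construction, so their number decides nothing there. Over the 3 groups 1 of 100 drawn splits, the real one, reached the 878 probes, and these splits ignored the slides as well. The highest other, 709, came from a split that kept the controls together and mixed the S1 and S2 arrays.

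Fewer probes passed in S1 (612) than in S2 (1476), while the direct comparison called 0. That S1-4 alone held the S1 count down cannot be told apart from the loss of an array, since the count was 557 without S1-4 and 376, 622 and 277 without S1-1, S1-2 and S1-3. The bound set for this test was wrong, because leaving out 3 of the 4 S1 arrays, each alone, lowers the count. The variance of the fold changes, taken from separate sets of arrays to leave out the noise of single arrays, was 1.52 times larger in S2. It was 1.20 to 2.01 times larger with any array left out. A larger response to S2 remains a candidate explanation, but effects shared by the arrays of a slide can remain in this variance. The counts in S1 and S2 were 393 and 482 without S2-1, 425 and 519 without S2-2, 386 and 765 without S2-3, and 744 and 1544 without S2-4. With slide as a block they were 555 and 1049. The gap narrowed most without S2-1 or S2-2, but leaving out an S2 array also leaves S2 with fewer arrays than S1. How far the gap rests on single S2 arrays or on the slides therefore stays open. A difference of dose or composition between the batches was not tested.

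The treated arrays were on average dimmer than the control arrays, by 0.76 on the log2 scale in S1 and 0.33 in S2. If brightness made the changes, the slope of each probe on brightness within groups should predict a large share of them. The median share it predicted was 0.0166 for the called probes of S1 and -0.0200 for those of S2. Probes are called in part for a small spread within groups, which keeps such slopes small. These shares therefore cannot decide whether brightness made the changes. With brightness as a covariate 215 probes passed in S1, 165 of them among the 612, and 1842 in S2, 1227 of them among the 1476. The S1 count fell and the S2 count rose, so whether part of the S1 count rests on brightness, or the loss on the overlap of brightness with the groups, stays open.

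The probes of several cyp2 genes and of rbm48 rose by similar amounts, most of them cross-hybridising. In the cyp2 run on chromosome 5, 1 of the 3 probes named specific, that of cyp2c19, rose in both mixtures, but the specificity rests on the name alone, so a cross-hybridising source stays open for it too. For the 25 cross-hybridising probes that rose by over 2 on the log2 scale in both mixtures, of which 6 lie in the run, the deviations from the group means correlated at a median of 0.699, against a 95th percentile of 0.185 and a median of 0.0692 in 1000 random sets. These probes may report a common transcript, but genes regulated together would give the same correlation, so which of them rose stays open.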

How the results depend on the processing

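The tests with array brightness, with specific probes only, without the 3 arrays that stood apart, with normexp on the median signal and without 3 doubtful list matches were chosen after the data were seen. Of the values of called lists under settings other than leaving out 1 array, 250 kept their call and 55 lost it, and with 1 array left out 200 kept it and 16 lost it. For called named genes 841 kept it, 348 lost it and 20 turned sign, and with 1 array left out 713 kept it and 343 lost it. With 1 array left out, probes changed numbered 277 to 744 in S1, 482 to 1673 in S2, 0 to 1 between the mixtures and 359 to 989 over the 3 groups. The correlation of fold changes was 0.691 to 0.796, and list calls numbered 6 to 13 in S1, 7 to 9 in S2 and 0 to 0 between the mixtures. Where no cause is named below, the cause was not tested. Signal over background limits the dim genes, such as cxcl9, well above background on 0 of 4 control arrays. Leaving out the 3 list matches left the list calls at 9, 9 and 0.

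Without a filter on dim probes 21 of the 35 named genes in S1 and 42 of the 53 in S2 passed, 35 and 44 under quantile normalization or in the authors' table, with scaling to the median 31 and 51, with array weights 33 and 53, and without the 3 arrays 19 and 31. Quantile normalization and the authors' table both gave 761, 1429 and 0 probes changed in S1 against control, probes changed in S2 against control and probes changed in S2 against S1, within 1.5 times of the main counts. Scaling to the median called 1 probe in S2 against S1. Without a filter r was 0.732, and on probes well above background on all 12 arrays r was 0.800, with 2 probes and 2 lists in S2 against S1. Array weights gave 4026 probes in S2 and 2437 over the 3 groups. An intensity trend gave 977 in S1, 1 in S2 against S1 and 1414 over the 3 groups. On the arrays of the compared groups alone S1 had 288. Requiring a log2 change of at least 1 left 190, 257 and 262 over the 3 groups by construction, an adjusted p under 0.1 gave 1382, 2845, 2 between the mixtures and 1886, and tests per gene, with fewer tests, gave 121, 270 and 161. Brightness as a covariate gave 215 in S1, 527 over the 3 groups and r = 0.821. Specific probes alone, fewer by construction, gave 341, 839, 2 and 539, with 14 list calls in S1 and 2 in S2 against S1. Without the 3 arrays the F-test gave 462 and r was 0.738. An estimated correlation left 0 list calls in S1 and 0 in S2. fry called 17 lists in S1 in 1 direction, and 21 and 22 in either direction. With the controls split, r was 0.323, 0.581, 0.480, 0.532, 0.468 and 0.571, with 2 control arrays behind each mixture.

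The replicate numbers were not taken to pair the arrays, since no label ties a number to a shared clutch or day and not every pair of arrays with the same number deviated together. Their deviations correlated at -0.0293 to 0.362 (median 0.144, against -0.0477 for different numbers), 8 of 12 pairs lay over 0.1, and 8 of 12 arrays correlated best with their own number. Arrays of different groups on the same slide correlated at a median of 0.156 (9 of 15 pairs over 0.1). Across slides the median was -0.0663 (3 of 33 pairs over 0.1). Several pairs with the same number also shared a slide, so number and slide cannot be fully told apart. With the replicate number as a block 540 probes passed over the 3 groups, 420 in S1, 1100 in S2 and 0 between the mixtures. The liver list in S1 (adjusted p = 0.0606) and the photoreceptor list in S2 (adjusted p = 0.0624) did not pass with it. Nor did 13 of the 35 named genes in S1, namely acod1la, slc34a3, sec61b, pinopsin100496420, lrrc52, ldlr, rps19, hsp30c, rarb, plg, kng1, amn and ift88, and 12 of the 53 in S2, namely lrrd1, me1, angptl4, scarb1, nr1h4, mcl1, ctrb1, pvalb, gucy2f, krt78.3, vcan and oxt.

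Normexp with an offset of 50 called 28 probes in S1, 29 in S2, 28 over the 3 groups and 1 list in S2 against S1, and with no offset 28, 29, 28 and 1, with r = 0.644. All 131 spots that lay below their local background had one marked as an outlier by the scanner software, and the lowest percentile of the corrected signals came to 56.8 to 1316.7 per array, against 35 to 50 before. It was 1316.7 on C-4 and 1056.3 on S2-1, above the 75th percentiles of their deposited signals, 499.51 and 516.53. On such arrays this form raised the floor above much of the signal. With the marked local backgrounds set to the array's median the lowest percentile came to 54.7 to 59.8, and 653 probes passed in S2, 510 over the 3 groups and 1 list in S2 against S1, with 493 in S1. The first form moved the median of all probes by 0.27 in S1 and 0.19 in S2 (0.27 and 0.15 with no offset), and the higher share of calls to 96.4% and 93.1%, from 66.5% and 48.1%. The last form moved the median by 0.18 and 0.12 and gave shares of 80.1% and 61.7%.

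Signs turned mostly under normexp, in values not taken relative to those medians. In S1, with the offset and without, they were aqp10 (0.0902 and 0.0362), c4h3orf84 (0.24 and 0.19), lrrc52 (0.28 and 0.24), rarb (0.23 and 0.20) and ift88 (0.22 and 0.19). In S2, with the offset, they were atp13a-like (0.0808), cryga.1 (0.14), stpg4 (0.10), lrrd1 (0.11), cnp (0.0878), lrrc14b (0.36, 0.26 without offset), ctrb1 (0.10), gucy2f (0.0283) and ift88 (0.0420). Between the mixtures nim1k came to -0.31, -0.43 without offset and -0.0533 with the local backgrounds replaced, and aqp10 to -0.10 and -0.10. The uncalled alb in S1 came to -0.0580 with array weights, -0.0645 without C-1, -0.0481 without S1-4, -0.24 with brightness and -0.0226 without the 3 arrays. The uncalled hmox1 in S2 came to 0.00916 without the 3 arrays. The list means turned sign for neurons in S1 (0.16 and 0.20) and photoreceptors in S2 (0.03 and 0.00) under normexp, with and without offset.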

Other observations

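The test on neighbouring genes and the choice of the genes in this part came only after the results were seen.

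The cyp2 run on chromosome 5 of the gene table's assembly holds 30 protein-coding genes, and 13 of them have a tested probe. They were counted by their place between the 2 ends of the run, not by gene family. Of the 13, cyp2f1, cyp2a13l and cyp2c19 carry a cyp2 symbol and the others only a LOC placeholder. The probes of 7 of these 13 rose in both mixtures, 1 named specific (cyp2c19) and 6 cross-hybridising. The largest rise in the run was on the probe of LOC100491441, by 5.81 ± 0.22 in S1 and 6.05 ± 0.22 in S2 (SE, n = 4 arrays per group, limma adjusted p = 3.55e-08 and 2.42e-08), followed by LOC100495517 (3.17 and 3.33). The remaining 2 specific probes, of LOC100493928 and LOC100491603, stood at 0.69 and 0.40 in S1 (adjusted p = 0.0669 and 0.314) and rose by 0.75 and 0.77 in S2 (adjusted p = 0.0321 and 0.041). LOC100494741 and LOC100495056, whose probes cross-hybridise, stood at 0.20 and 0.01 in S1 (adjusted p = 0.407 and 0.99).

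Of the called probes, 476 of 612 in S1 and 1179 of 1476 in S2 matched no gene, against 81.3% of all tested probes. The specific probe GT_EA519_mRNA_specific_001556 rose by 10.09 in S1 and 10.39 in S2 and was well above background on 1 of 4 control arrays, and GT_EA519_mRNA_specific_007084 rose by 6.67 and 6.66. Among the falls, GT_EA519_mRNA_specific_003840 stood at -3.22 in S1 and GT_EA519_mRNA_specific_006609 at -2.14 in S2, each with a fall in the other mixture as well.

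A hypothesis was that neighbouring genes may respond together outside the cyp2 run. Neighbours here are genes next to each other among the 3923 with a tested specific probe, so other genes may lie between them. Of these 3923, 221 passed in S2 and formed 6 neighbouring pairs called in 1 direction, against a mean of 6.19 and a 95th percentile of 10 in 10000 shuffles. In S1 102 passed and formed 4 pairs, against a mean of 1.38 and a 95th percentile of 3 (share with as many 0.0487). The mixtures gave different answers and the pairs are few, so whether neighbours respond together stays open.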
